A study of Caenorhabditis elegans with 9 samples.

How the data were processed

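Total RNA of whole young adult wild-type (N2) C. elegans grown on E. coli OP50, E. coli HT115 or Comamonas DA1877 was labelled and hybridised to Affymetrix C. elegans arrays, with 3 arrays per diet. The deposited values are on the log2 scale. Per the submitters' processing notes, they were made with Affymetrix Expression Console and RMA, which corrects the background, applies quantile normalisation and summarises the probes of each probe set by median polish. No versions are stated for these tools. The values fitted that description: array medians lay between 7.08 and 7.15, and values between 3.71 and 15.5. Scanner files were not used here, so there are no detection calls, and dim probe sets are set against 3 Trpn control probe sets. For arrays there is no sequencing depth, and their number limits the precision.

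The table holds 22625 probe sets. The 77 array controls were left out of the tests and used as checks, which left 22548. Of these, 20766 were tied to a single gene symbol, 887 to several and 895 to none, giving 17118 genes. Symbols were updated through the gene identifiers of the WBcel235 gene table, used for names only, which held 20701 of the single-gene probe sets. Probe sets of suffix _s_at (5484) or _x_at (1227) have probes that can match more than 1 transcript. The dimmest probe sets were kept.

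Differences between diets were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided), with a mean per diet and all 9 arrays in a single fit. P-values were adjusted by the Benjamini-Hochberg method over the 22548 probe sets of each comparison, and a probe set was called at an adjusted p under 0.05 with no minimum fold. The 3 arrays of a diet were treated as independent biological replicates, as the series design describes them. Replicate numbers were not used as pairs in the fit, and the labels do not say what they mark. Residuals of same-numbered arrays correlated over 0.1 in all 3 pairs of OP50 and HT115 (0.159, 0.105 and 0.424). Arrays of different diets and different numbers reached 0.342, above 0.159 and 0.105. No same-numbered pair with DA1877 correlated over 0.1 (-0.311 to 0.049), so for HT115 against OP50 a value with the replicate number as a block is given where it changed a call. Yet the molting list lay above its diet's mean in replicate 2 and below it in replicate 3 of all 3 diets, so pairing with DA1877 stays possible. Block values for the comparisons with DA1877 are given with the processing alternatives. Control probe sets were compared by exact permutation of 3 against 3 arrays, for which 0.1 is the smallest possible p. Overlaps of calls are given beside the count for independent lists and beside 100 simulated data sets of unchanged groups with the same shared arrays.

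A total of 38 gene lists, written before the data were examined, were tested with camera at its preset correlation of 0.01 between genes, for lists of at least 3 measured genes, with adjustment over all 114 tests. Camera tests a list against all other genes measured, so a list called higher is higher relative to those genes. Each gene was represented by its probe set with the highest mean. Of the 417 list members given by name, 33 were not matched. The fry test and camera with an estimated correlation were run beside it. Members called are counted after adjustment over all probe sets and also after adjustment over the list alone. The lists cover the propionate shunt, the B12-dependent propionate pathway, the methionine and folate cycles, amino acid and lipid metabolism, detoxification, immunity, chaperones, ribosome and respiratory chain, cuticle and molting, germline and embryo, and tissue markers.

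Genes were named by a rule set before the data were examined. It takes, per comparison, the 10 largest called differences in each direction among single-gene probe sets whose arrays did not overlap, up to 4 called members with the largest differences from each list described, and every member of the propionate shunt, B12-dependent pathway and methionine and folate lists.

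Alternatives tried were the replicate number as a block, only the 6 arrays of the 2 diets compared, leaving out the dimmest 40% of probe sets, quantile normalisation again, centring each array on its median, eBayes with trend and robust settings, an unmoderated linear model, leaving out suffix _s_at and _x_at, a 2-fold minimum, leaving out each array in turn, the mean of all probe sets of a gene, fry, and camera with an estimated correlation. Centring each array on its 18 hybridisation controls was added after seeing the data, as was the same with OP50 replicate 3 left out. Where the text gives the number of alternatives under which a gene or list was called, the replicate block, the 2-fold minimum, the estimated correlation and the centring without OP50 replicate 3 are not counted. The procedure was tested on simulated data with 50 changed probe sets at each of 4 sizes. At a log2 change of 0.25, 12%, 4% and 12% were recovered in the 3 comparisons, at 0.5 74%, 80% and 78%, at 1 96%, 100% and 100%, and at 2 all. False calls were 6 of 147, 8 of 150 and 7 of 152. The data gave 2090 to 5841 calls, and with fewer changed probe sets the adjusted threshold is stricter. The recovered shares therefore need not hold for the reported comparisons. Simulated probe sets were also drawn independently of each other.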

Results

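Transcript levels were measured in whole young adult wild-type (N2) Caenorhabditis elegans fed 3 bacterial diets. The reference diet was Escherichia coli OP50, the usual laboratory food of the worm. The others were E. coli HT115, the strain commonly used for RNA interference by feeding, and Comamonas DA1877, a soil bacterium. Each diet was sampled by 3 arrays, which the series design describes as biological replicates. Each array reports log2 signal for 22548 probe sets of worm transcripts, which name 17118 genes. Every value below is a normalised log2 signal or a difference of such signals. Means are given ± SD with n = 3 arrays per diet. Differences are given ± SE from the linear model, and adjusted p-values are from that model. The number of arrays limits the precision.

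Arrays of the same diet resembled each other more than arrays of different diets. Correlations across probe sets lay between 0.996 and 0.998 within a diet and between 0.984 and 0.995 between diets. The first principal component held 59.4% of the variance and separated the DA1877 arrays from all E. coli arrays. The second component held 18.8% and separated OP50 from HT115. On the third component, with 8.25%, OP50 replicate 3 stood at -17.4, against 1.96 and 9.17 for the other OP50 arrays. HT115 replicate 3 lay in the same direction, at -8.57, against 9.05 and 4.29 for the other HT115 arrays. The 18 hybridisation control probe sets, which detect transcripts added before hybridisation, averaged 10.135 ± 0.103 on DA1877, 10.005 ± 0.019 on HT115 and 9.886 ± 0.179 on OP50. Centring each array on these controls would therefore lower every difference between DA1877 and OP50 by 0.249, between HT115 and OP50 by 0.119 and between DA1877 and HT115 by 0.130. Without OP50 replicate 3, whose controls averaged 9.68, the first 2 would be 0.145 and 0.0153. Poly-A controls, added before labelling, differed in the same direction, by 0.269 between DA1877 and OP50 (exact p = 0.3) and 0.183 between HT115 and OP50 (exact p = 0.1), or 0.174 and 0.0891 without that array. The actin 3' minus 5' signal, a sign of RNA quality, was 0.15 higher on DA1877 than on OP50 (exact p = 0.1, the smallest possible). OP50 replicate 3 read -0.061 for it, against 0.123 and 0.113 on the other OP50 arrays. The same measure for GAPDH was 0.045 higher on DA1877 than on OP50 (exact p = 0.3). With arrays centred on the hybridisation controls, the median difference over all probe sets would go from 0.037 to -0.21, from 0.0068 to -0.11 and from 0.017 to -0.11. Differences below are on the authors' scale, and called gene lists whose mean changes sign under that centring are named where they occur. With OP50 replicate 3 left out, the centring changed the sign of no called list between HT115 and OP50, and between DA1877 and OP50 only of the germline and C-type lectin lists.

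The comparison of DA1877 with OP50 asked which transcripts differ when the worms eat Comamonas instead of the reference diet. The largest difference was in acdh-1, the acyl-CoA dehydrogenase of the propionate shunt, which was 203-fold lower on DA1877 (5.97 ± 0.26 against 13.64 ± 0.08, difference -7.67 ± 0.11, adjusted p = 7.21e-14). Its level on DA1877 was close to that of the Trpn control probe sets, which have no target in the sample and whose brightest member read between 4.98 and 5.15 on those arrays. The cystathionine gamma-lyase gene cth-1 was 28.1-fold lower (adjusted p = 7.21e-14), the arginine kinase gene argk-1 26.4-fold lower (adjusted p = 6.81e-13) and the C-type lectin gene clec-47 20.9-fold lower (adjusted p = 1.11e-11). At the other end, pud-4 and pud-3, named for their higher protein levels in insulin receptor mutants, were 23-fold and 21.3-fold higher on DA1877 (adjusted p = 4.15e-12 and 9.42e-11). Further genes among the 10 largest increases were T19C9.8 (8.67-fold), srlf-34 (8.61-fold), Y49G5A.1 (6.92-fold), sysm-1 (6.48-fold), C32H11.4 (6.31-fold), nspg-7.2 (6.31-fold), irg-5 (5.95-fold) and clc-11 (5.80-fold). The largest decreases also included F21C10.9 (17.1-fold), K10D3.4 (10.6-fold), H20E11.2 (9.92-fold), the cuticle collagen gene bli-1 (8.57-fold), clec-258 (8.44-fold) and hphd-1 (8.29-fold). The rule for naming these genes took only probe sets whose 3 DA1877 arrays lay entirely above or below the 3 OP50 arrays.

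Genes of propionate breakdown by the shunt fell together on DA1877. All 5 measured members were called lower, with a mean difference of -3.09 (camera adjusted p = 1.10e-13; adjusted p = 0.0817 with an estimated correlation). The 5 were also called when adjusted over the list alone. Beside acdh-1, the hydroxyacid-oxoacid transhydrogenase gene hphd-1 (-3.05 ± 0.07), the enoyl-CoA hydratase gene ech-6 (-1.88 ± 0.06), the hydrolase gene hach-1 (-1.87 ± 0.09) and the semialdehyde dehydrogenase gene alh-8 (-0.98 ± 0.07) fell. The canonical propionate pathway, which depends on vitamin B12, was not called as a list (camera adjusted p = 0.293). Of its 6 genes, mmaa-1 was lower (-0.68 ± 0.08, adjusted p = 2.61e-05), and the other 5, pcca-1, pccb-1, mce-1, mmcm-1 and mmab-1, differed by -0.12 to 0.03 and did not pass the test.

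The methionine and folate cycles also fell as a list on DA1877, with 11 of 19 genes called lower and 2 called higher, and the same counts when adjusted over the list alone (mean difference -0.65, camera adjusted p = 2.79e-08; adjusted p = 0.0817 with an estimated correlation). Genes lower on DA1877 included cth-1, the transporter gene pmp-5 (-2.88 ± 0.10), the methionine synthase reductase gene mtrr-1 (-1.47 ± 0.07) and the methylenetetrahydrofolate reductase gene mthf-1 (-0.85 ± 0.06). The others were dao-3 (-0.83 ± 0.09), the methionine synthase gene metr-1 (-0.78 ± 0.08), the adenosylhomocysteinase gene ahcy-1 (-0.59 ± 0.07), the serine hydroxymethyltransferase gene mel-32 (-0.55 ± 0.06), sams-5, sams-4 and pmt-2. The cystathionine beta-synthase gene cbs-1 went the other way (1.78 ± 0.07, adjusted p = 7.59e-10), as did cth-2 by 0.22 ± 0.06 (adjusted p = 0.0286), although that difference was -0.03 after centring on the hybridisation controls and was called under 11 of 16 alternatives. Differences for sams-1, pmt-1, alh-3, cbs-2, folr-1 and tyms-1 lay between -0.12 and 0.01 and did not pass. Of the 11 diet and lipid regulators, the nuclear hormone receptor genes nhr-114 (-2.37 ± 0.08, adjusted p = 2.19e-10) and nhr-68 (-1.62 ± 0.09, adjusted p = 2.17e-08) were the 2 called, both lower.

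**Figure D1:**
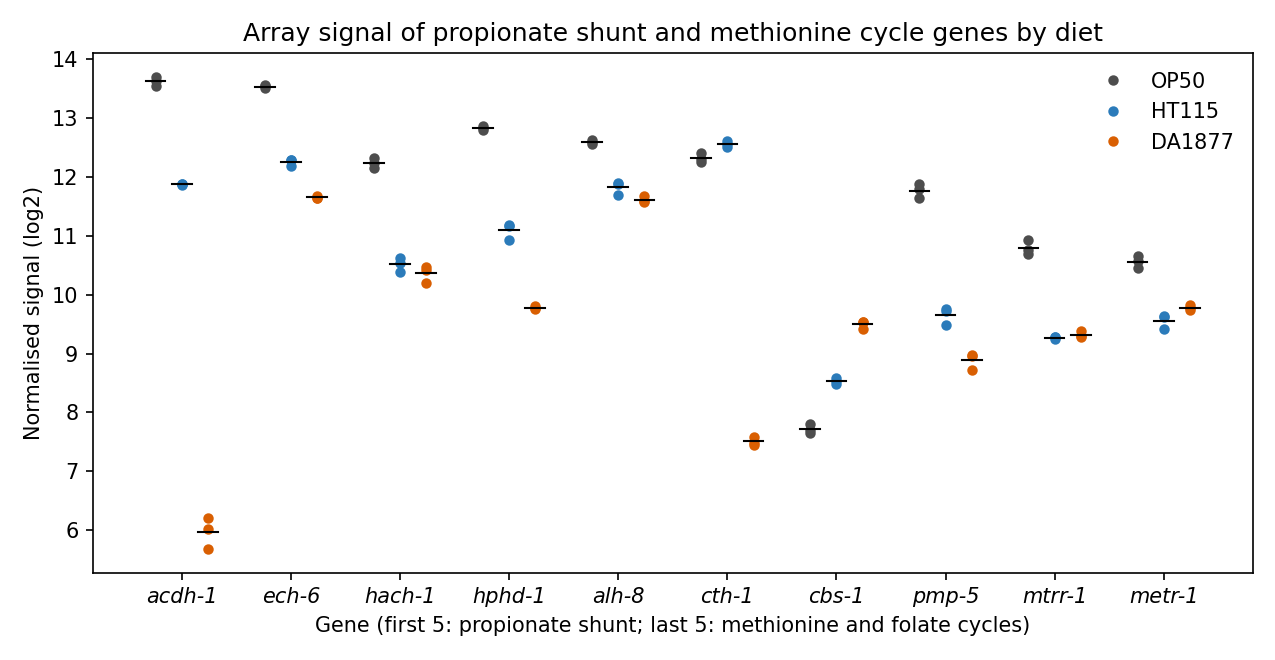
Normalised log2 signal (vertical axis) of the 5 propionate shunt genes and 5 methionine and folate cycle genes (horizontal axis), with a point per array (3 per diet) coloured by diet and a bar at each diet's mean. On DA1877 acdh-1 stood at 5.97 and cth-1 at 7.51, against 13.64 and 12.32 on OP50, while cth-1 on HT115 stood at 12.57 and cbs-1 was higher on both other diets than on OP50.

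The molting and cuticle collagen lists were lower on DA1877 than on OP50, with part of their genes called. Of 23 molting genes, 13 were called lower and 0 higher (15 lower and 1 higher when adjusted over the list alone), with a mean difference of -0.89 (camera adjusted p = 8.50e-12; adjusted p = 0.0817 with an estimated correlation). The protease inhibitor gene mlt-11 (-2.85 ± 0.08), the apical matrix gene noah-1 (-2.82 ± 0.08), the hedgehog-related gene qua-1 (-2.72 ± 0.10) and acn-1 (-2.49 ± 0.09) fell most. Cuticle collagens were split, with 64 of 145 called lower and 18 called higher (65 and 20 when adjusted over the list alone; mean -0.44, camera adjusted p = 3.72e-11, adjusted p = 0.155 with an estimated correlation). The 4 with the largest differences were bli-1 (-3.10 ± 0.14), sqt-1 (-2.57 ± 0.13), col-49 (-2.27 ± 0.13) and col-109 (-2.24 ± 0.08). Among 53 hedgehog-related genes, which share 1 gene (qua-1) with the molting list, 20 were lower and 2 higher, also when adjusted over the list alone (camera adjusted p = 7.74e-09; adjusted p = 0.0817 with an estimated correlation), with wrt-4 (-2.38 ± 0.11), grl-7 (-2.29 ± 0.13) and grl-15 (-2.28 ± 0.14) next to qua-1.

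Genes of the oocyte and the eggshell were higher on DA1877, and part of the markers of several somatic tissues were lower. Of 24 oocyte and eggshell genes, 21 were called higher and 0 lower (23 higher when adjusted over the list alone), with a mean difference of 0.37 (camera adjusted p = 5.74e-11; adjusted p = 0.153 with an estimated correlation). The eggshell genes perm-2 (0.76 ± 0.08) and perm-4 (0.59 ± 0.07) and the oocyte maturation genes oma-2 (0.54 ± 0.07) and lin-41 (0.49 ± 0.09) differed most. These differences were small. With each array centred on the hybridisation controls, a setting chosen after seeing the data, 1 of the 24 was called, or 6 with OP50 replicate 3 left out. Germline mitosis and meiosis genes were higher in 12 of 37 cases and lower in 0 (13 when adjusted over the list alone; camera adjusted p = 5.96e-04, adjusted p = 0.353 with an estimated correlation), led by cyb-3 (0.39 ± 0.06) and mcm-5 (0.36 ± 0.07). Their mean of 0.16 became -0.09 after that centring. All 5 measured vitellogenin genes, which encode yolk proteins, rose, vit-1 by 1.01 ± 0.07 and the others by less. The probe sets of vit-4 and vit-5 were of suffix _x_at, whose probes can match more than 1 transcript. The list's mean was 0.53 (camera adjusted p = 7.41e-05, adjusted p = 0.0817 with an estimated correlation), and all 5 genes were called when adjusted over the list alone. After centring on the hybridisation controls their mean was 0.28 and vit-2, vit-4 and vit-5 were not called (adjusted p = 0.219 to 0.391), though vit-4 was with OP50 replicate 3 also left out. Muscle genes were lower in 16 of 30 cases and higher in 0 (18 when adjusted over the list alone; camera adjusted p = 7.18e-09, adjusted p = 0.106 with an estimated correlation), with troponin T gene tnt-3 at -1.24 ± 0.09 and myosin gene myo-1 at -0.70 ± 0.08. Of 17 intestinal genes 8 were lower and 1 higher, and of 49 neuronal genes 9 were lower and 1 higher (camera adjusted p = 0.0011 and 0.0049; adjusted p = 0.275 and 0.167 with an estimated correlation). Adjusted over the list alone, these were 8 and 1 for the intestine and 9 and 2 for neurons. The neuronal call did not hold without probe sets of suffix _s_at or _x_at (adjusted p = 0.0995).

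The DAF-16 class II and infection response lists were higher on DA1877, and 0 of 5 cytosolic heat shock genes were called. The lysozyme and antimicrobial peptide list was not called in either direction (camera adjusted p = 0.665). Its members went both ways, with 16 of 66 genes called higher and 9 lower (16 and 10 when adjusted over the list alone). Of 8 measured genes known as class II targets, which the transcription factor DAF-16 represses, 5 were higher and 0 lower, including dod-22 (1.75 ± 0.08) and dod-24 (1.21 ± 0.07) (camera adjusted p = 4.44e-04; adjusted p = 0.0817 with an estimated correlation), and the list alone gave the same 5. Of 9 infection response genes, 4 were higher and 1 lower (4 and 2 when adjusted over the list alone; camera adjusted p = 0.0105, adjusted p = 0.25 with an estimated correlation), with irg-5 at 2.57 ± 0.09 and K08D8.5 at 1.59 ± 0.08. This call did not hold without probe sets of suffix _s_at or _x_at (adjusted p = 0.0995). Glutathione S-transferase genes were higher in 13 of 43 cases and lower in 2 (14 and 2 when adjusted over the list alone; camera adjusted p = 0.00801, adjusted p = 0.226 with an estimated correlation), led by gst-38 (2.51 ± 0.07) and gst-20 (1.57 ± 0.08). The list's mean of 0.21 became -0.03 after centring on the hybridisation controls. The lysozyme gene lys-4 fell by 2.53 ± 0.08. In lipid metabolism, the stearoyl-CoA desaturase genes fat-7 (-2.91 ± 0.10) and fat-5 (-1.35 ± 0.10) and the elongase gene elo-4 (2.29-fold) were lower, in a list with 4 genes lower and 2 higher of 18, also when adjusted over the list alone (camera adjusted p = 0.0429; adjusted p = 0.226 with an estimated correlation). This list was called under 13 of 18 alternatives, with adjusted p up to 0.157.

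In all, DA1877 and OP50 differed in 3940 of 22548 probe sets, 1820 higher on DA1877 (1564 genes) and 2120 lower (1742 genes). Of these, 86 higher and 397 lower differed by 2-fold or more, and the median size of a called difference was 0.41. The 3 arrays of each diet did not overlap in 32.2% of probe sets, against 10% by chance. Higher calls made up 46.2% of all calls, 58.8% with each array centred on its median and 6.73% with each array centred on the hybridisation controls, a setting that gave 341 higher and 4729 lower and was chosen after seeing the data. With OP50 replicate 3 also left out, the centring gave 564 higher and 3803 lower (12.9% higher). Without probe sets of suffix _s_at or _x_at, the counts were 1051 and 1313.

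The comparison of HT115 with OP50 asked how far a second E. coli strain differs from the reference diet. The largest difference was again a decrease, in clec-47, which was 35.7-fold lower on HT115 (7.28 ± 0.09 against 12.44 ± 0.25, adjusted p = 1.43e-11). It was followed by the acyl-CoA dehydrogenase gene acdh-2 (adjusted p = 5.27e-10), the methionine sulfoxide reductase gene msra-1 (5.29-fold, adjusted p = 1.46e-10), pmp-5 (4.33-fold), srh-237 (4.16-fold), DH11.2 (3.90-fold), nhr-114 (3.88-fold), C09B8.4, clc-24 (3.58-fold) and acdh-1 (3.39-fold). The genes higher on HT115 were led by pud-3 (7.95-fold, adjusted p = 1.58e-08) and pud-4 (7.93-fold, adjusted p = 1.11e-09). Next came the lipase gene lipl-2 (4.08-fold), srlf-34 (3.22-fold), hrg-3, gst-38 (2.93-fold), C17H12.6 (2.83-fold), hrg-7 (2.79-fold), the alcohol dehydrogenase gene adh-1 (2.70-fold) and txt-4 (2.66-fold). The level of hrg-3 was 6.13 ± 0.35 on HT115 and 4.45 ± 0.10 on OP50, below the brightest Trpn control on each OP50 array, so no fold is given. No fold is given for acdh-2 and C09B8.4 either. Their HT115 levels of 5.10 ± 0.10 and 4.71 ± 0.07 were close to and below the highest Trpn control value on those arrays (5.05). For pud-3 the 3 HT115 arrays read the same value, 10.62.

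The propionate shunt and the methionine and folate cycles were also lower on HT115 than on OP50. All 5 propionate shunt genes were called lower, also when adjusted over the list alone (mean -1.45, camera adjusted p = 4.83e-14; adjusted p = 0.0817 with an estimated correlation), from acdh-1 at -1.76 ± 0.11, hphd-1 at -1.74 ± 0.07 and hach-1 at -1.72 ± 0.09 to ech-6 at -1.28 ± 0.06 and alh-8 at -0.77 ± 0.07. In the methionine and folate cycles 9 of 19 genes were lower and 3 higher (10 and 4 when adjusted over the list alone; mean -0.35, camera adjusted p = 1.41e-04, adjusted p = 0.123 with an estimated correlation). The lower genes included pmp-5 (-2.11 ± 0.10), mtrr-1 (-1.53 ± 0.07), metr-1 (2.01-fold), sams-5 (-0.76 ± 0.09), mthf-1 (-0.65 ± 0.06), tyms-1 (-0.60 ± 0.08), mel-32 (-0.58 ± 0.06), ahcy-1 (-0.50 ± 0.07) and sams-4 (-0.38 ± 0.07). The gene cbs-1 was higher on HT115 (0.82 ± 0.07). Small increases of cth-1 (0.25 ± 0.07, adjusted p = 0.0376) and cth-2 (0.24 ± 0.06, adjusted p = 0.0315) were called under 7 of 17 and 10 of 16 alternatives, with adjusted p up to 0.627 and 0.653, and cth-1 had an adjusted p of 0.0604 with the replicate number as a block. In the vitamin B12-dependent pathway, mmaa-1 was lower (-0.98 ± 0.08, adjusted p = 3.41e-06), and the other 5 genes differed by -0.09 to 0.19 without passing the test (list camera adjusted p = 0.973).

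Oocyte and eggshell genes, which were higher on DA1877 than on OP50, were lower on HT115. Of 24 oocyte and eggshell genes, 19 were called lower than on OP50 and 0 higher (22 lower and 1 higher when adjusted over the list alone), with a mean of -0.31 (camera adjusted p = 1.36e-13; adjusted p = 0.121 with an estimated correlation) and nos-2 (-0.47 ± 0.08), egg-1 (-0.47 ± 0.08), cpg-2 (-0.44 ± 0.07) and pie-1 (-0.42 ± 0.07) as the largest. Germline mitosis and meiosis genes were lower in 13 of 37 cases and higher in 0 (28 lower when adjusted over the list alone; mean -0.23, camera adjusted p = 3.62e-12, adjusted p = 0.108 with an estimated correlation), for example mcm-3 (-0.43 ± 0.07) and pcn-1 (-0.34 ± 0.06). Vitellogenins were higher in 2 of 5 cases (4 when adjusted over the list alone; vit-1 0.49 ± 0.07; camera adjusted p = 0.00104, adjusted p = 0.104 with an estimated correlation), and vit-1 was not called after centring on the hybridisation controls (adjusted p = 0.0606), but was with OP50 replicate 3 also left out. The other called member, vit-5, was called under 7 of 16 alternatives, and lost its call when any 1 of the OP50 or HT115 arrays was left out (adjusted p = 0.0522 to 0.108). Molting genes were lower in 7 of 23 cases and higher in 2 (8 and 2 when adjusted over the list alone; camera adjusted p = 0.00233, adjusted p = 0.254 with an estimated correlation), with noah-1 at -0.79 ± 0.08 and mlt-11 at -0.63 ± 0.08. Cuticle collagens included 22 higher and 5 lower of 145 (28 and 11 when adjusted over the list alone; camera adjusted p = 4.44e-04, adjusted p = 0.396 with an estimated correlation), their mean of 0.07 became -0.05 after centring on the hybridisation controls, and the fry test did not call them (adjusted p = 0.0733). The muscle, intestine and neuron lists were not called on HT115 (camera adjusted p = 0.125, 0.267 and 0.603), and their means, all above 0, were below 0 after that centring, but only that of neurons with OP50 replicate 3 left out.

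Part of the glutathione S-transferase, iron and heme, and infection response genes were higher on HT115. Of 43 glutathione S-transferase genes 13 were higher and 0 lower (14 when adjusted over the list alone; camera adjusted p = 2.86e-08, adjusted p = 0.0817 with an estimated correlation), with gst-38 at 1.55 ± 0.07 and gsto-1 at 1.22 ± 0.10. Of 10 iron and heme genes 5 were higher and 0 lower (6 and 1 when adjusted over the list alone; mean 0.59, camera adjusted p = 8.92e-07, adjusted p = 0.0992 with an estimated correlation), including hrg-3, hrg-7 (1.48 ± 0.06), the heme importer gene hrg-4 (1.28 ± 0.10) and the heme transporter gene hrg-1 (1.01 ± 0.07). Of 9 infection response genes 6 were higher and 0 lower (7 when adjusted over the list alone; camera adjusted p = 2.43e-06, adjusted p = 0.0992 with an estimated correlation), with irg-5 at 1.30 ± 0.09, irg-3 at 1.21 ± 0.10 and K08D8.5 at 1.18 ± 0.08. DAF-16 class II genes were higher in 4 of 8 cases, also when adjusted over the list alone (dod-22 1.35 ± 0.08; camera adjusted p = 3.76e-05, adjusted p = 0.0817 with an estimated correlation).

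HT115 and OP50 differed in 2090 probe sets, fewer than either comparison with DA1877, of which 710 were higher on HT115 (603 genes) and 1380 lower (1203 genes). A difference of 2-fold or more was seen in 41 of the higher and 55 of the lower probe sets, and the arrays did not overlap in 24.8% of probe sets, against 10% by chance. Higher calls made up 34% of all calls, 49.1% after another quantile normalisation and 13.5% with arrays centred on the hybridisation controls. With OP50 replicate 3 also left out, that last share was 26%. The count of lower calls was 649 without HT115 replicate 2, 848 without HT115 replicate 3, 663 without OP50 replicate 1 and 806 without OP50 replicate 2, and that of higher calls 450 without HT115 replicate 2 and 460 without OP50 replicate 1.

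The direct comparison of DA1877 with HT115 tested whether the responses to the 2 diets differ. The largest decreases were in the same genes as between DA1877 and OP50: acdh-1 was 60.1-fold lower on DA1877 than on HT115 (adjusted p = 7.11e-13), argk-1 34-fold (adjusted p = 3.95e-13) and cth-1 33.4-fold (adjusted p = 7.58e-14). Further large decreases were in clec-258 (13.4-fold), H20E11.2 (12.1-fold), F22B8.7 (7.48-fold), fat-7 (7.29-fold), K10D3.4 (7.22-fold), F21C10.9 (6.12-fold) and dao-4 (5.48-fold). The genes higher on DA1877 differed less, from nspg-7.2 at 5.78-fold (adjusted p = 1.55e-08) and T19C9.8 at 3.39-fold to clc-11, sysm-1, pud-4, warf-1, the innexin gene inx-2, srlf-34, pud-3 and Y49G5A.1, which were 2.64-fold to 3.04-fold higher. The level of nspg-7.2 was 8.20 ± 0.27 on DA1877, 5.67 ± 0.12 on HT115 and 5.54 ± 0.11 on OP50.

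Within the propionate shunt, 4 of 5 genes were lower on DA1877 than on HT115, also when adjusted over the list alone (mean -1.64, camera adjusted p = 6.79e-06; adjusted p = 0.104 with an estimated correlation): acdh-1, hphd-1 (-1.31 ± 0.07), ech-6 (-0.60 ± 0.06) and alh-8 (-0.21 ± 0.07), while hach-1 differed by -0.15 ± 0.09 (adjusted p = 0.236). The call of alh-8 (adjusted p = 0.0459) held under 5 of 16 alternatives, with adjusted p up to 0.159. The methionine and folate list was not called (camera adjusted p = 0.153). Its members included 6 called lower and 3 higher (6 and 4 when adjusted over the list alone), with cth-1 at -5.06 ± 0.07, pmp-5 at -0.77 ± 0.10 and dao-3 at -0.72 ± 0.09 against cbs-1 at 0.96 ± 0.07, tyms-1 at 0.48 ± 0.08 and sams-5 at 0.29 ± 0.09. In addition, cbs-2 (-0.27 ± 0.09), pmt-1 (-0.22 ± 0.07) and mthf-1 (-0.19 ± 0.06) were lower. These small differences were called under 7 of 17, 8 of 16 and 7 of 16 alternatives, with adjusted p up to 0.132, 0.141 and 0.110, and that of sams-5 under 9 of 16, with adjusted p up to 0.473. The call of tyms-1 was lost only after centring on the hybridisation controls (adjusted p = 0.0526). Differences for mtrr-1 (0.05 ± 0.07) and metr-1 (0.22 ± 0.08) did not pass, nor did those for ahcy-1, mel-32, sams-1, sams-4, cth-2, alh-3, folr-1 and pmt-2, which lay between -0.20 and 0.03. In the vitamin B12-dependent pathway mmaa-1 was higher on DA1877 than on HT115 (0.30 ± 0.08, adjusted p = 0.0105; adjusted p = 0.398 after centring on the hybridisation controls), and the other 5 genes, at -0.15 to 0.10, did not pass (list camera adjusted p = 0.619).

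Oocyte, germline, cuticle and muscle lists separated DA1877 from HT115. All but 1 of the 24 oocyte and eggshell genes were called higher on DA1877 (23, and 24 when adjusted over the list alone), by 0.68 on average (camera adjusted p = 3.23e-19; adjusted p = 0.0992 with an estimated correlation), with nos-2 (0.94 ± 0.08) and oma-2 (0.91 ± 0.07) first, and 23 were also called with arrays centred on the hybridisation controls. Germline mitosis and meiosis genes were higher in 28 of 37 cases and lower in 0 (34 when adjusted over the list alone; mean 0.38, camera adjusted p = 4.26e-13, adjusted p = 0.104 with an estimated correlation). Lower on DA1877 were 12 of 23 molting genes with 0 higher (12 and 1 when adjusted over the list alone; mean -0.71, camera adjusted p = 5.92e-09, adjusted p = 0.0992 with an estimated correlation) and 73 of 145 cuticle collagens with 8 higher (81 and 11 when adjusted over the list alone; camera adjusted p = 3.23e-19, adjusted p = 0.0992 with an estimated correlation). Likewise lower were 22 of 53 hedgehog-related genes with 2 higher (24 and 2 when adjusted over the list alone; camera adjusted p = 7.05e-09, adjusted p = 0.0817 with an estimated correlation) and 24 of 30 muscle genes with 0 higher (24 when adjusted over the list alone; mean -0.32, camera adjusted p = 3.03e-10, adjusted p = 0.0992 with an estimated correlation). Examples are mlt-11 (-2.22 ± 0.08), bli-1 (-2.43 ± 0.14), wrt-4 (-2.09 ± 0.11) and myo-1 (-0.69 ± 0.08). Of 10 iron and heme genes 6 were lower on DA1877 and 1 higher, also when adjusted over the list alone (mean -0.60, camera adjusted p = 2.45e-04, adjusted p = 0.153 with an estimated correlation), with hrg-7 at -1.86 ± 0.06.

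**Figure D2:**
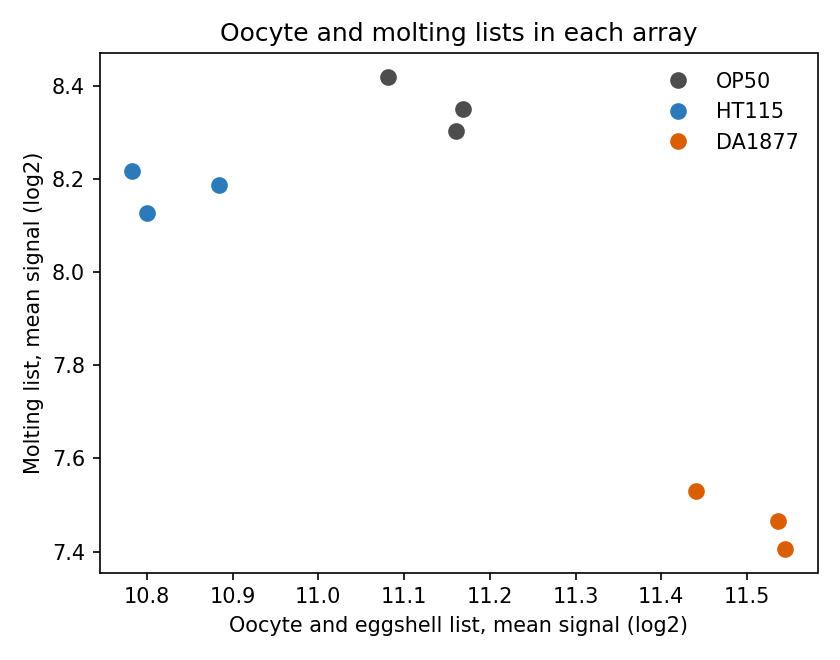
Mean log2 signal of the 24 oocyte and eggshell genes (horizontal axis) against that of the 23 molting genes (vertical axis) in each of the 9 arrays, a point per array, coloured by diet. The DA1877 arrays lay at 11.44 to 11.54 for oocyte genes and 7.41 to 7.53 for molting genes, the OP50 arrays at 11.08 to 11.17 and 8.30 to 8.42, and the HT115 arrays at 10.78 to 10.88 and 8.13 to 8.22.

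DA1877 and HT115 differed in 5841 probe sets, 3341 higher on DA1877 (2799 genes) and 2500 lower (2070 genes), of which 55 and 303 differed by 2-fold or more. The arrays did not overlap in 38.3% of probe sets, against 10% by chance. Higher calls made up 57.2% of all calls and 23.8% with arrays centred on the hybridisation controls, when 816 probe sets were higher and 2614 lower. With OP50 replicate 3 also left out, these were 1595 and 4731 (25.2% higher). That array enters this comparison only through the spread shared by all arrays. Without probe sets of suffix _s_at or _x_at, the counts were 1804 and 1548.

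The overlap of calls was also counted across comparisons. DA1877 was higher than each E. coli diet in 1201 probe sets and lower than each in 1654, against 270 and 235 for independent lists of these sizes. Simulated unchanged groups gave 0, but such groups give almost no calls, so that 0 does not measure the effect of shared arrays. The 2 comparisons share the DA1877 arrays, and their fold changes correlated across probe sets at r = 0.81, against 0.50 in the simulation (covariance 0.085 against 0.0042). Without DA1877 replicate 1 the count of probe sets higher than each E. coli diet was 797, and with arrays centred on the hybridisation controls it was 188. Against OP50, 392 probe sets were higher and 425 lower on both other diets, with 57.3 and 130 for independent lists and again 0 in the simulation (r = 0.44 against 0.50, covariance 0.031 against 0.0042). Part of these overlaps may come from the shared arrays, since 3 arrays cannot be split into groups of at least 2. A further 276 probe sets were higher on DA1877 and lower on HT115 than on OP50, against 111 for independent lists, and they included 17 of the 24 oocyte and eggshell genes and 9 of the 37 germline genes. With arrays centred on the hybridisation controls this count was 32, against 21.3 for independent lists, with 0 genes of either list. With OP50 replicate 3 also left out it was 57, against 31.8, with 2 oocyte and 0 germline genes. With any other array left out instead, the count fell to between 8 and 22, with 0 genes of either list. It was 18 and 17 without OP50 replicate 1 or 2, against 18.4 and 18.5 for independent lists. Without HT115 replicate 2 it was 8, against 6.64. The opposite pattern was seen in 55 probe sets, against 66.8 for independent lists.

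**Figure D3:**
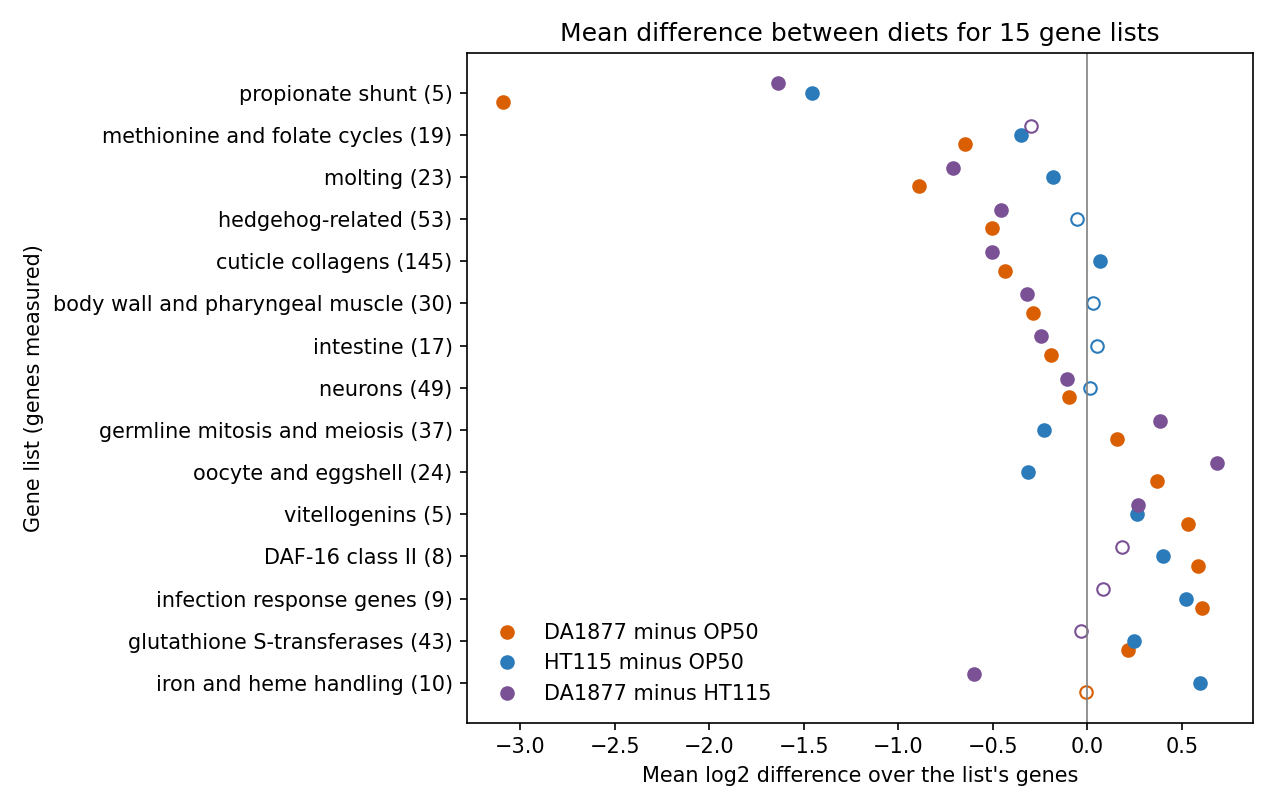
Mean log2 difference (horizontal axis) over the genes of each of 15 lists (vertical axis, with the number of genes measured) in the 3 comparisons, shown by colour. Filled points are lists called by camera at its preset correlation and open points are lists that were not called. The oocyte and eggshell list stood at 0.37 on DA1877 and -0.31 on HT115 relative to OP50, and the propionate shunt at -3.09 and -1.45. With arrays centred on the hybridisation controls, the DA1877 minus OP50 means of the germline and glutathione S-transferase lists, the HT115 minus OP50 means of the collagen, muscle, intestine and neuron lists and the DA1877 minus HT115 mean of the infection list fall below 0. With OP50 replicate 3 also left out, those of the germline, neuron and infection lists do. With arrays centred on their medians, the DA1877 minus OP50 mean of the iron and heme list and the DA1877 minus HT115 mean of the glutathione S-transferase list rise above 0.

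Across the 38 lists tested in each comparison, camera called 25 for DA1877 against OP50 (7 higher, 18 lower), 20 for HT115 against OP50 (12 higher, 8 lower) and 17 for DA1877 against HT115 (3 higher, 14 lower). With the correlation between genes estimated from the arrays, 0 lists passed in each comparison, although 12, 9 and 13 had an unadjusted p under 0.05, and the directional fry test called 26, 22 and 21. The size of the correlation is not the only reason for these losses. For UDP-glucuronosyltransferases (DA1877 against OP50) the estimate was 0.0083, under the preset 0.01, yet the unadjusted camera p went from 3.66e-05 to 0.00528. Without probe sets of suffix _s_at or _x_at, camera called 16, 13 and 11, and the propionate shunt then had too few measured genes to be tested.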

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

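The tests of stage at harvest and of OP50 replicate 3 were set before their results were seen, while those of germline RNA, scaling, the propionate shunt and the other splits of the arrays were chosen after, as were the further stage lists read for OP50 replicate 3 and the centring without it. The hybridisation controls, which lie outside the comparisons, averaged 0.249 higher on DA1877 than on OP50 (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). They were set apart for this difference between diets in transcripts added to each sample, and OP50 replicate 3 had the lowest value, 9.68, without which the difference is 0.145. Poly-A controls were 0.269 higher on DA1877 (exact permutation p = 0.3), or 0.174 without that array.

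On DA1877, 13 and 12 of 23 molting genes were called lower than on OP50 and HT115, as were 64 and 73 of 145 collagens (18 and 8 higher), and 21 and 23 of 24 oocyte genes were called higher. With an estimated correlation, none of these lists was called. Dilution of all somatic transcripts by germline RNA is argued against as the whole cause of the molting decrease. Between DA1877 and HT115 the molting list fell further than the muscle, neuron and intestine lists (difference of means -0.511, 95% interval -0.863 to -0.183 over genes). That interval treats genes as independent. A part for dilution stays open, since the muscle, neuron and intestine genes together also fell (mean -0.198) while oocyte genes were higher. Scaling between arrays is argued against for oocyte genes between DA1877 and HT115, where 23 of 24 were called higher after centring on the hybridisation controls. For molting genes this centring cannot decide. It lowers every difference between these diets by 0.130, and 12 molting genes were called lower before and after it. For oocyte genes between DA1877 and OP50 scaling may account for many of the calls. There 1 of 24 was called after the centring, or 6 with OP50 replicate 3 left out (mean 0.24, median SE 0.101). With all arrays the list mean went from 0.37 to 0.12 (SD over genes 0.14), while the median SE went from 0.075 to 0.126, so both a smaller difference and a wider spread ended the calls. A difference in stage at harvest cannot be told apart from diet: within diets the oocyte and molting means correlated at r = -0.630 (permutation p = 0.111; -0.184 without the 2 farthest arrays), but the molting deviations followed the replicate number in all 3 diets (0.040 to 0.063 in replicate 2, -0.050 to -0.062 in replicate 3), so the 9 arrays are not independent in this test, and an effect of diet itself also stays open.

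Propionate shunt genes were lower on DA1877 and HT115 than on OP50. Unusual OP50 arrays are argued against as the whole cause of the decrease on DA1877, since 4 of the 5 genes also differed between DA1877 and HT115, or 3 without alh-8, whose call held under 5 of 16 alternatives. The gene hach-1 did not differ between them. For the decrease on HT115 this comparison cannot decide, because it leaves out the OP50 means. Probes shared with other transcripts are argued against for 2 genes, acdh-1 and hach-1, whose called probe sets are not of suffix _s_at or _x_at. For hphd-1, ech-6 and alh-8 the test cannot decide, because all their probe sets are of those suffixes. An effect of diet may underlie the pattern, as a hypothesis found and examined on the same data.

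OP50 replicate 3 lay apart from the other OP50 arrays. A different point of development cannot be told apart from other causes. Its collagen mean deviated by -0.0597 and its oocyte mean by 0.035, both under the bound of 0.1 set to argue against it, but that bound covered too few lists, since spermatogenesis genes deviated by -0.161 and embryonic genes by 0.101. In those lists OP50 replicate 2 deviated by 0.158 and -0.0822, so they do not single out OP50 replicate 3. Weaker hybridisation cannot be told apart either, as probe-set brightness explained a share of 0.177 of the deviation of OP50 replicate 3, against 0.0053 to 0.15 in the other arrays. HT115 replicate 3 lay in the same direction on the third principal component. Residuals of OP50 replicate 3 and HT115 replicate 3 correlated at 0.424. A cause shared by arrays of the same number was not tested and stays open.

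For each comparison, the real split of the 6 arrays was the 1 of 10 splits that gave as many calls, with 3940, 2090 and 5841 called for DA1877 against OP50, HT115 against OP50 and DA1877 against HT115, and 0 as the highest of the other splits. The 10 splits are too few for a share under 0.05.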

How the results depend on the processing

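Centring on the hybridisation controls was chosen after seeing the data, and the other alternatives before. Of 62 list calls, 41 held under every alternative but camera's estimated correlation, and of 426 named gene values that were called, 327 were called under every alternative that gave a value. Camera compares a list with the other genes, and both centrings shift all genes of an array alike. List calls that held under them therefore say little about scaling. The germline list (DA1877 against OP50) kept its call although its mean was -0.09 after centring on the hybridisation controls. Counts of calls below are higher and lower for DA1877 against OP50, HT115 against OP50 and DA1877 against HT115, then shared against OP50, then shared against both E. coli diets. Of the 9 arrays, 4 correlated best in their residuals with an array of their own number. With the replicate number as a block, cth-1 (HT115 against OP50) had an adjusted p of 0.0604, and no other gene value or list printed for that comparison changed its call. In the other comparisons the block gave an adjusted p of 0.0638 for alh-8, 0.0554 for cbs-2, 0.0692 for mthf-1 and 0.0439 for metr-1 (DA1877 against HT115), and 0.0527 for the diet and lipid regulators (DA1877 against OP50). All counts stayed within 1.5 times the reported ones with the replicate number as a block (1789 and 2100, 709 and 1304, 3271 and 2481 for the 3 comparisons), without the dimmest 40% of probe sets, with quantile normalisation again, with median centring and with trend and robust eBayes.

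With a 2-fold minimum they were 86 and 397, 41 and 55, 55 and 303, 27 and 46, and 20 and 270. Without probe sets of suffix _s_at and _x_at, which leaves fewer probe sets to test, they were 1051 and 1313, 432 and 633, 1804 and 1548, 247 and 231, and 638 and 1021, with 16, 13 and 11 lists called. The hypodermis and seam list (DA1877 against OP50) then had a mean of -0.0629 and its test turned upward (adjusted p = 0.894), and the cause was not tested. Centring on the hybridisation controls gave 341 and 4729 for DA1877 against OP50, 221 higher for HT115 against OP50, 816 higher for DA1877 against HT115, and 123 and 188 shared higher. With OP50 replicate 3 also left out, likewise chosen after, these were 564 and 3803, 446, 1595 (and 4731 lower), and 195 and 322, with 2872 shared lower against both E. coli diets. The centring with all arrays lowered every difference and also widened the spread (median SE of oocyte genes from 0.075 to 0.126). It also turned cth-2 to -0.0269 and msp-142 to -0.0105 for DA1877 against OP50. The unmoderated model gave 376 and 639 for HT115 against OP50 and 250 and 228 shared against OP50, and a fit of only the 6 arrays compared, with fewer samples, gave 912 lower for HT115 against OP50. Camera with the correlation estimated called 0, 0 and 0 lists, with 12, 9 and 13 at an unadjusted p under 0.05 and 26, 22 and 21 called by fry.

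Leaving out 1 array at a time gave 1245 to 1962 higher and 1699 to 2204 lower for DA1877 against OP50, 450 to 838 and 649 to 1617 for HT115 against OP50, 2527 to 3563 and 1903 to 2713 for DA1877 against HT115, 299 to 487 and 297 to 520 shared against OP50, and 797 to 1197 and 1342 to 1703 shared against both E. coli diets. For HT115 against OP50, lower calls were 649 without HT115 replicate 2, 848 without HT115 replicate 3, 663 without OP50 replicate 1 and 806 without OP50 replicate 2, higher calls were 450 without HT115 replicate 2 and 460 without OP50 replicate 1, and 797 shared higher is without DA1877 replicate 1. The propionate shunt list had too few genes without suffix _s_at and _x_at, and the 2-fold minimum and unmoderated model gave no list values. The Trpn controls read at most 4.80 to 5.15, which limits how far a decrease toward that level can be measured.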

Other observations

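The test of a graded response was chosen only after the result was seen. Lists not described above are given here by comparison, with the camera adjusted p. For calls lost under an alternative other than the estimated correlation or the block, the number of alternatives that called the list is given.

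Between DA1877 and OP50, UDP-glucuronosyltransferase genes were lower in 23 of 64 cases and higher in 7 (24 and 9 when adjusted over the list alone; ugt-17 -1.68; adjusted p = 1.49e-04, adjusted p = 0.0817 with an estimated correlation). Gut proteases were lower in 9 of 23 cases and higher in 1 (asp-13 -1.75; adjusted p = 1.14e-04, adjusted p = 0.112 with an estimated correlation) and organelle chaperones lower in 7 of 11 (10 when adjusted over the list alone; pdi-2 -0.65; adjusted p = 8.67e-06, adjusted p = 0.123 with an estimated correlation). Branched-chain amino acid breakdown was lower in 3 of 10 cases (5 when adjusted over the list alone; adjusted p = 0.0029, adjusted p = 0.188 with an estimated correlation), fatty acid oxidation lower in 5 of 21 and higher in 4 (adjusted p = 0.0379, adjusted p = 0.290 with an estimated correlation; called under 10 of 18) and the respiratory chain lower in 2 of 39 (0 when adjusted over the list alone; adjusted p = 0.00562, adjusted p = 0.475 with an estimated correlation; called under 16 of 18, not by fry, adjusted p = 0.0667, nor without suffix _s_at and _x_at, adjusted p = 0.0998). Histones were lower in 5 of 26 cases and higher in 2 (adjusted p = 0.0357, adjusted p = 0.455 with an estimated correlation; called under 11 of 18). The diet and lipid regulators, with 2 of 11 members called, had an adjusted p of 0.0479 as a list (adjusted p = 0.375 with an estimated correlation; called under 8 of 18, adjusted p up to 0.157). Hypodermis and seam genes were lower in 6 of 13 cases and higher in 1, with a mean of -0.53 and a median of 0.03 (adjusted p = 0.00921, adjusted p = 0.235 with an estimated correlation; called under 17 of 18, but not without suffix _s_at and _x_at, adjusted p = 0.894). C-type lectins were higher in 34 of 220 cases and lower in 14 (clec-139 1.80; adjusted p = 0.0479, adjusted p = 0.543 with an estimated correlation; called under 5 of 18), and their mean of 0.06 became -0.19 after centring on the hybridisation controls. Aromatic amino acid breakdown was not called as a list (adjusted p = 0.411), with 6 of 11 genes higher and 3 lower.

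Between HT115 and OP50, aromatic amino acid breakdown was higher in 5 of 11 cases and lower in 1 (6 and 2 when adjusted over the list alone; kynu-1 0.62; adjusted p = 0.00285, adjusted p = 0.241 with an estimated correlation; called under 17 of 18), while branched-chain breakdown was lower in 3 of 10 (adjusted p = 0.00184, adjusted p = 0.167 with an estimated correlation; called under 17 of 18) and diet and lipid regulators lower in 3 of 11 (adjusted p = 0.00435, adjusted p = 0.226 with an estimated correlation). Spermatogenesis genes were higher in 2 of 35 cases (adjusted p = 1.09e-04, adjusted p = 0.275 with an estimated correlation) and hypodermis and seam genes lower in 5 of 13 and higher in 1 (6 and 1 when adjusted over the list alone; adjusted p = 0.0474, adjusted p = 0.353 with an estimated correlation; called under 8 of 18, with a mean of -0.17 that was -0.014 without suffix _s_at and _x_at, adjusted p = 0.942). Lists with a positive mean that was negative after centring on the hybridisation controls, but not with OP50 replicate 3 also left out, were lysozymes and antimicrobial peptides (12 higher and 3 lower of 66, 15 and 4 when adjusted over the list alone; adjusted p = 0.00124, adjusted p = 0.210 with an estimated correlation), C-type lectins (17 higher and 10 lower of 220; adjusted p = 2.62e-04, adjusted p = 0.263 with an estimated correlation; called under 17 of 18, not by fry, adjusted p = 0.0697), major sperm proteins (0 of 23 called; adjusted p = 0.0241, adjusted p = 0.592 with an estimated correlation; called under 12 of 17, not by fry, adjusted p = 0.0713) and early zygotic embryo genes (2 higher of 45, 1 when adjusted over the list alone; adjusted p = 0.0474, adjusted p = 0.567 with an estimated correlation; called under 8 of 18, not by fry, adjusted p = 0.110).

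Between DA1877 and HT115, lipases were lower in 6 of 24 cases and higher in 1 (lips-3 -1.22; adjusted p = 0.00233, adjusted p = 0.104 with an estimated correlation), gut proteases lower in 8 of 23 and higher in 1 (10 and 1 when adjusted over the list alone; asp-8 -1.43; adjusted p = 3.00e-04, adjusted p = 0.123 with an estimated correlation) and UDP-glucuronosyltransferases lower in 17 of 64 and higher in 4 (18 and 4 when adjusted over the list alone; ugt-63 -1.21; adjusted p = 0.00916, adjusted p = 0.112 with an estimated correlation; called under 17 of 18). Organelle chaperones were lower in 5 of 11 cases (6 when adjusted over the list alone; adjusted p = 0.00295, adjusted p = 0.254 with an estimated correlation; called under 17 of 18), intestinal genes in 9 of 17 (11 when adjusted over the list alone; adjusted p = 4.35e-05, adjusted p = 0.197 with an estimated correlation), and neuronal genes in 10 of 49 with 1 higher (adjusted p = 0.00177, adjusted p = 0.142 with an estimated correlation; called under 17 of 18). Fatty acid synthesis genes were lower in 7 of 18 cases and higher in 3 (adjusted p = 0.0156, adjusted p = 0.167 with an estimated correlation), hypodermis and seam genes lower in 6 of 13 and higher in 2 (adjusted p = 0.0479, adjusted p = 0.353 with an estimated correlation; called under 11 of 18, with a mean of -0.36 that was -0.049 without suffix _s_at and _x_at, adjusted p = 0.996), and vitellogenins higher in 2 of 5 (4 when adjusted over the list alone; vit-1 0.52; adjusted p = 0.0178, adjusted p = 0.167 with an estimated correlation; called under 15 of 17). The DAF-16 class I, cytochrome P450, cytosolic heat shock, ribosomal protein and insulin-like peptide lists were not called in any of the 3 comparisons, and 0 of 75 ribosomal protein genes and 0 of 5 heat shock genes were called (1 heat shock gene higher on HT115 than on OP50 when adjusted over the list alone).

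A graded response, with HT115 between OP50 and DA1877, may hold for the propionate shunt, methionine and folate genes as a hypothesis. Of 14 such genes lower on HT115 than on OP50, 6 were lower again on DA1877 than on HT115, a share of 0.429 (95% interval 0.177 to 0.711), and 2 were higher. The 6 include alh-8 and mthf-1, called under 5 of 16 and 7 of 16 alternatives, and with 1 array left out at a time the share was 0.286 to 0.4, with 4 of 14 as the lowest (without OP50 replicate 1, HT115 replicate 1 or 2, or any of the DA1877 replicates). Among all 1380 probe sets lower on HT115 the share was 0.171, and 897 were higher on DA1877 than on HT115. The interval holds 0.5, so the test left this open. The interval also treats the genes as independent. The genes were chosen by the same HT115 arrays that are then compared with DA1877. Such a choice can lower the share and raise the count of probe sets higher on DA1877.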
